A study of Arabidopsis thaliana with 12 samples.

How the data were processed

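Gene expression was measured in petioles of 4-week-old Arabidopsis thaliana plants with 12 Affymetrix ATH1 arrays, 1 per sample. Plants had been grown at a red to far-red light ratio (R/FR) of 2.2 and were then kept for 2 h in high R/FR or in low R/FR (0.2), with a mock spray or a spray of 0.1 mM jasmonic acid (JA). Each sample pooled 3 petiole pieces of about 5 mm, and 100 ng of RNA entered the labelling reaction, per the labels' protocols. The 4 groups held 3 samples each, which the labels call biological replicates.

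The deposited table holds one value per probe set and array on the log2 scale. The authors made these log2 values with RMA, per the submitters' processing notes, and the software version is not given in the sources used here. The scale was judged from the values, which ran from 2.37 to 14.0 with nearly equal quartiles on every array. RMA sets the arrays to a common distribution, so a shift of all transcripts in one direction would not be visible, and it compresses changes of probe sets near the lower end of the scale. No new normalization was applied. Of the 22810 probe sets, 64 Affymetrix controls were left out of the tests and 22746 were tested. The precision of every value is limited by the number of arrays, 3 per group.

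Genes were named through GEO's platform annotation and a RefSeq gene table of assembly TAIR10.1, matched on the gene number. Of the tested probe sets, 13513 were paired with 1 gene, 503 with several and 8730 were not listed in that annotation, so they are unnamed here and enter only the counts. Of the 1-gene probe sets, 13436 were matched to the gene table and 77 kept the annotation's symbol. They stand for 13356 genes, and where a gene had several probe sets the one with the highest mean stood for it. Positions are not given because no genome build is named in the files. Many well known genes of the JA and shade responses, all JAZ repressors among them, lie on probe sets unnamed here: of the 283 genes on the 20 lists fixed before the data were examined, 41 could be named. Only the lists auxin response (5 of 22 genes) and cell wall loosening (7 of 19) reached the minimum of 5 members for a test. For the other lists, members are given singly.

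A linear model with one mean per group was fitted to all 12 arrays with limma 3.58.1 (R 4.3.3, statmod 1.5.0). Its moderated two-sided tests were adjusted by the Benjamini-Hochberg method over all probe sets within a contrast, and a probe set was called at an adjusted p under 0.05. The residual degrees of freedom were 8, and 13.0 with the moderation. The contrasts were JA against mock in each light condition, low against high R/FR with each spray, and the interaction, which is the JA effect in low R/FR minus that in high R/FR. Errors given as SE come from this model, and errors given as SD are over the 3 arrays of a group.

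To compare response sizes, probe sets called for the average JA effect or the average low R/FR effect were taken, raised and lowered ones apart. The median of their interaction was computed, and limma's fry tested whether they moved one way on balance. Beside it, the residuals of the model without interaction were regrouped in a permutation with 100 draws, the real one included. In this balanced design the average effects are uncorrelated with the interaction, so the choice of probe sets does not favour a sign. Gene lists were tested with limma's camera, with the correlation between genes estimated from the data and adjusted over the 10 pairs of a list and a contrast. A further 16 lists were drawn up from the annotation's gene names after the table had been received and before any group difference was computed, and were tested the same way over 80 pairs. They merge or extend the fixed lists for JA, shade and auxin, flavonoids, glucosinolates and the XTH and expansin families, or hold gene families and other groups (defence signalling, calmodulin-like calcium sensors, gibberellin perception, UDP-glycosyltransferases, tau glutathione transferases, beta-glucosidases, SWEET transporters, the CYP71B family, autophagy genes, nuclear photosynthesis genes and plastid-encoded genes).

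The rule for named genes was fixed before the data were examined. For each contrast it takes the 8 largest rises and the 8 largest falls among called 1-gene probe sets, for pairwise contrasts only those whose 3 values in one group all lie beyond the 3 of the other. It adds the 4 members of each fixed list with the largest change, called or not, and 11 marker genes, of which only PDF1.2 could be named. A gene named under one contrast may be given under others. Genes named outside this rule are marked as chosen after their values were seen.

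The functions were tested on simulated arrays with the real means and spreads of the 22746 probe sets, of which 67, 67 and 66 per contrast were changed by 0.5, 1 and 2 on the log2 scale. At a 2-fold change 97.0% were recovered for the JA effect in high R/FR, 94.0% for that in low R/FR, 95.5% for each low R/FR effect and 86.6% for the interaction. At a log2 change of 0.5 the shares were 52.2%, 43.3%, 55.2%, 59.7% and 16.4% in the order high R/FR JA effect, low R/FR JA effect, low R/FR with mock, low R/FR with JA and interaction. Between 4.26% and 6.21% of the calls were false. Camera was tested on simulated lists of 7 genes, with 20 of the lists raised 2-fold in turn for each of the 5 contrasts. It called 20 of 20 raised lists and 0 of 100 unchanged ones in each contrast. The simulated genes were independent, and recovery of lists with correlated genes was not simulated.

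The alternatives were the replicate number as a block, arrays centred on their medians, a repeated quantile normalization, leaving out the dimmest 30% of probe sets, eBayes with trend and robust, array weights, fits of only the groups compared, one value per gene, leaving out each array, stricter thresholds, and for lists camera with a preset correlation of 0.01 and fry. A covariate for RNA quality was added later, made from the 3' minus 5' log2 signals of the actin and GAPDH control probe sets. No array was left out.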

Results

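Expression was measured in petioles of Arabidopsis plants exposed for 2 h to high or low R/FR light, with a mock spray or a JA spray. A low R/FR is the light signal of neighbouring plants, and JA is a hormone of defence against insects and necrotrophic fungi. The series addressed the crosstalk between these signals. There were 3 arrays in each of the 4 groups. Correlations between arrays of one group ran from 0.992 to 0.996 across all probe sets. The difference between 3' and 5' log2 signal of the actin control, a sign of RNA quality, was 3.21 ± 0.08 (SD, n = 3) with mock in high R/FR, 3.38 ± 0.23 with JA in high R/FR, 3.11 ± 0.11 with mock in low R/FR and 3.33 ± 0.64 with JA in low R/FR. Replicate 3 of the last group lay highest of all 12 arrays, at 3.97. For the GAPDH control the difference was 1.61 ± 0.13 and 1.64 ± 0.04 with mock in high and low R/FR, and 1.87 ± 0.13 and 1.94 ± 0.44 with JA. The means of both controls were thus higher with JA than with mock in each light condition. In low R/FR the JA arrays spread widely, with 2.68, 3.34 and 3.97 for actin and 1.61, 1.77 and 2.45 for GAPDH. Replicate 1 of this group lay lowest of all 12 arrays for actin, so the higher means there lean on replicate 3.

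The first comparison asked what JA changed in high R/FR. Enzymes of anthocyanin synthesis rose: all 4 measured members of that fixed list were called, and all 4 also when adjusted over the list alone. DFR, dihydroflavonol reductase, went from 5.46 ± 0.73 to 10.00 ± 0.07 (log2, SD, n = 3), a 23.3-fold rise (log2 4.54, SE 0.28, adjusted p = 2.72e-07). The glycosyltransferase UF3GT rose 13.4-fold, AT4G14090 (listed as UGT75C1) 11.4-fold and the malonyltransferase AT5MAT 8.19-fold. Genes of JA breakdown rose as well, 3 of 4 measured, and 3 when adjusted over the list alone. AT2G38240 (JOX4) rose 14.4-fold (log2 3.84, SE 0.53), AT5G05600 (JOX2) 7.70-fold and JRG21 (JOX3) 2.17-fold; these encode JA oxidases. The largest rise of a named gene was that of AT4G17470, 33.2-fold (log2 5.05, SE 0.20, adjusted p = 5.39e-09), followed after DFR by AT1G54020 at 20.3-fold. AT5G44050 rose 13.8-fold, 4CL8 13.7-fold and AT4G29700 12.7-fold. Among genes of glucosinolate and tryptophan synthesis, BCAT4, an aminotransferase of methionine-derived glucosinolates, rose 3.33-fold, AT2G04400 (IGPS) 2.71-fold and UGT74B1 1.49-fold. OPCL1, a ligase of JA synthesis, rose 1.72-fold, and the glutaredoxin gene GRX480 1.60-fold.

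Genes of cell wall loosening fell with JA in high R/FR. Of 7 measured members 4 were called lower, and 5 when adjusted over the list alone. The median log2 change was -0.72, and camera gave an adjusted p of 0.0126. The 27 genes of the XTH and expansin families, a wider list drawn up after the data had been received, had a median of -0.16 and were not called as a list (adjusted p = 0.296). The xyloglucan endotransglucosylase gene XTH19 had a log2 change of -1.36 (SE 0.29, adjusted p = 0.0127), the expansin genes EXPA8 -1.31 (SE 0.22, adjusted p = 0.00219) and EXPA15 -0.83 (SE 0.17, adjusted p = 0.0102). Outside the list, the pectin methylesterase gene ATPMEPCRB (-1.38) and the expansin gene EXPB1 (-1.19) were among the largest falls of named genes, with AT1G80280 (-1.19), AT5G22460 (-1.12) and AT4G32460 (-1.04). The transcription factor gene WRKY53 also fell (-1.27, SE 0.30, adjusted p = 0.0219). The antifungal defensin gene PDF1.2 had a log2 change of 0.87 with an SE of 1.22 (adjusted p = 0.822); its arrays spread widely within each group. In all, 1240 of 22746 probe sets were called, 777 higher and 463 lower with JA, of which 344 changed at least 2-fold. The 3 JA arrays all lay beyond the 3 mock arrays for 24.1% of probe sets, where chance gives 10%. The call of XTH19 was lost without high R/FR, mock replicate 3 or JA replicate 2, that of WRKY53 without JA replicate 2 or 3, that of EXPA15 without mock replicate 3, that of EXPB1 without mock replicate 2 or 3 or JA replicate 1 or 3, and that of UGT74B1 without any high R/FR array but JA replicate 2. Over all fits without 1 array the log2 changes ran from -1.52 to -1.10 for XTH19, from -1.53 to -0.81 for WRKY53, from -0.99 to -0.67 for EXPA15, from -1.49 to -0.99 for EXPB1 and from 0.45 to 0.67 for UGT74B1.

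The second comparison asked what JA changed in low R/FR. The anthocyanin genes rose again, 4 of 4, and 4 when adjusted over the list alone. DFR rose 20.0-fold (log2 4.32, SE 0.28, adjusted p = 6.66e-07), AT4G14090 10.9-fold, UF3GT 9.57-fold and AT5MAT 6.27-fold. Of the genes of JA breakdown, AT5G05600 rose 9.30-fold, AT2G38240 8.76-fold and JRG21 1.46-fold. AT4G17470 rose 28.1-fold and AT1G54020 13.5-fold. The lectin gene JAL23 rose 12.9-fold and AT3G51450 10.5-fold. BCAT4 rose 4.37-fold, AT2G04400 2.58-fold, GRX480 1.79-fold and OPCL1 1.60-fold. GH3.3, which encodes an enzyme that conjugates auxin to amino acids, rose 2.48-fold (log2 1.31, SE 0.22, adjusted p = 0.00371). XTH19 fell most among named genes (log2 -1.75, SE 0.29, adjusted p = 0.00319), followed by AT1G10640 (-1.29), AT1G80280 (-1.05) and AT4G18970 (1.99-fold lower); the actin gene ACT11 (-0.86), AT1G12570 (-0.86) and EXPA15 (-0.72) fell too. MYC4, a transcription factor gene of JA signalling, fell by 0.52 on the log2 scale (SE 0.11, adjusted p = 0.0196). The cell wall loosening genes were lower, with 2 of 7 called and 3 when adjusted over the list alone; the median log2 change was -0.59, and camera gave an adjusted p of 0.0242. This list call was lost without low R/FR, JA replicate 1 (adjusted p = 0.0546) or replicate 3 (0.0774), and with the RNA quality covariate (0.0517). WRKY53 had a log2 change of 0.37 (SE 0.30, adjusted p = 0.613) and PDF1.2 of 0.86 (SE 1.22, adjusted p = 0.803).

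In low R/FR 801 probe sets were called for JA, 560 higher and 241 lower. Without low R/FR, mock replicate 2 there were 526. In low R/FR, the calls of MYC4 and JRG21 were lost without mock replicate 1 or 3 or JA replicate 2, for MYC4 also without JA replicate 3 and for JRG21 without JA replicate 1. Those of EXPA15 and OPCL1 were lost without mock replicate 2 or 3 or JA replicate 2 of low R/FR or mock replicate 2 of high R/FR, for EXPA15 also without JA replicate 3 and for OPCL1 without JA replicate 1 of low R/FR. Over all fits without 1 array the log2 changes of EXPA15, OPCL1, MYC4 and JRG21 ran from -0.81 to -0.58, from 0.58 to 0.83, from -0.61 to -0.45 and from 0.45 to 0.67. The JA effects in high and low R/FR rest on different arrays, but their tests share one estimate of the spread per probe set. The calls are therefore not independent, and shared calls can exceed those of independent lists for that reason too. Called rises were shared for 473 probe sets, where independent lists would share 19.1, and called falls for 128, against 4.91. No probe set was called in opposite directions. Across all 22746 probe sets, which are not independent replicates, the 2 JA effects had a Pearson correlation of 0.80.

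**Figure D1:**
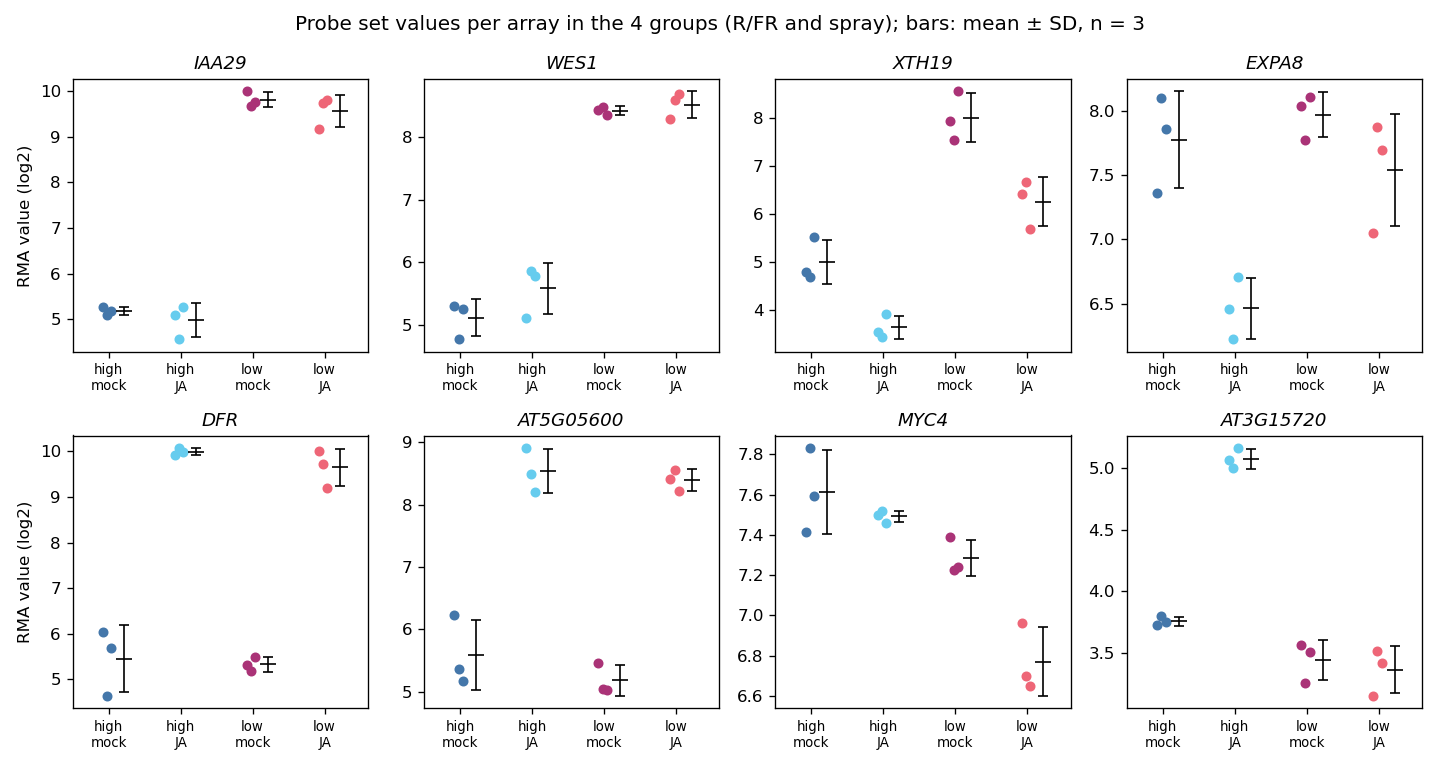
Log2 RMA values of 8 named genes (vertical axes, own scale per panel) on each of the 12 arrays, by light condition and spray (horizontal axis), with the mean and SD of the 3 arrays beside the points. IAA29 and WES1 are higher in both low R/FR groups, DFR and AT5G05600 in both JA groups, and AT3G15720 stands apart in high R/FR with JA, at 5.08 ± 0.08.

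The third comparison asked what low R/FR changed under mock spray. Auxin response genes rose: 4 of 5 measured members were called, and 4 when adjusted over the list alone, with a median log2 change of 1.65 and an adjusted p of 0.00227 by camera. IAA29, an Aux/IAA gene, went from 5.18 ± 0.09 to 9.81 ± 0.17 (log2, SD, n = 3), a 24.8-fold rise (log2 4.63, SE 0.18, adjusted p = 4.99e-08). WES1 (GH3.5), which like GH3.3 encodes an auxin-conjugating enzyme, rose 10.0-fold, GH3.3 3.03-fold and IAA30 3.15-fold, while GH3.1 had a log2 change of 0.23. Of the 4 measured shade avoidance markers, 2 were called and 3 when adjusted over the list alone: IAA29 and the homeobox gene HAT2, which rose 2.54-fold (log2 1.35, SE 0.21). The auxin synthesis gene YUC2 had a log2 change of 0.11 (SE 0.13, adjusted p = 0.790). Cell wall loosening genes were higher, with 2 of 7 called and 4 when adjusted over the list alone, a median log2 change of 0.64 and an adjusted p of 0.0328 by camera. The wider list of 27 genes of the XTH and expansin families, drawn up after the data had been received, had a median of 0.019 (-0.0028 after a repeated quantile normalization) and was not called (camera adjusted p = 0.420). XTH19 rose 8.02-fold (log2 3.00, SE 0.29, adjusted p = 5.50e-05) and XTH18 2.59-fold (log2 1.38, SE 0.33). MGL, methionine gamma-lyase, rose 6.90-fold. AT4G35720 rose 8.67-fold, AT4G03140 7.66-fold, AT5G57760 7.61-fold and AT5G12050 6.56-fold.

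Of named genes whose arrays did not overlap between the 2 groups, the largest falls in low R/FR with mock were those of the beta-glucosidase gene BGLU47 (log2 -1.79, SE 0.20, adjusted p = 0.000138), AT1G78170 (-1.77), AT1G54820 (-1.76), AT5G62130 (-1.71), AT4G33666 (-1.54), AT1G23390 (-1.47), AT5G62360 (-1.40) and AT1G74940 (-1.30). The JA signalling genes MYC3 and MYC4 had log2 changes of -0.44 (SE 0.13, adjusted p = 0.0782) and -0.33 (SE 0.11, adjusted p = 0.143). They missed the threshold over all probe sets, but these 2 of the 3 measured members of the MYC branch list were lower when adjusted over the list alone. FMA, a guard cell transcription factor gene and the only named member of the epidermis list, had -0.27 (SE 0.11, adjusted p = 0.243) and was lower only when adjusted over the list alone. The 4 anthocyanin genes missed the threshold in limma, also when adjusted over the list alone, with log2 changes from -0.39 to 0.03. In all 992 probe sets were called, 557 higher and 435 lower in low R/FR, of which 215 changed at least 2-fold. The arrays of the 2 groups did not overlap for 19.1% of probe sets, against 10% by chance. The count was 522 without high R/FR, mock replicate 2, 652 without mock replicate 3 of that light, 572 without low R/FR, mock replicate 2 and 517 without its replicate 3. The cell wall call was lost without high R/FR, mock replicate 1 (adjusted p = 0.0780), low R/FR, mock replicate 3 (0.0635) or low R/FR, JA replicate 1 (0.0546), with the RNA quality covariate (0.0517) and with the replicate number as a block (0.0665), while the call of XTH18 was lost without any mock array but low R/FR replicate 2 (log2 from 1.13 to 1.60).

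The fourth comparison asked what low R/FR changed under JA spray. IAA29 rose 24.1-fold (log2 4.59, SE 0.18, adjusted p = 3.23e-08), WES1 7.70-fold, GH3.3 4.52-fold and IAA30 2.88-fold. Of the auxin response genes 4 of 5 were called, and 4 when adjusted over the list alone (median log2 2.18, adjusted p = 0.00272 by camera). AT5G02580 rose 8.03-fold and ARL, which promotes cell expansion, 7.57-fold with a wide error (log2 2.92, SE 0.57). AT1G44830 rose 6.67-fold, AT4G03140 6.42-fold and AT5G57760 6.09-fold. Over fits without 1 array the log2 change of AT5G57760 ran from 2.01 to 3.11. Of the cell wall loosening genes 4 of 7 were called higher, and 6 when adjusted over the list alone (median log2 1.05, adjusted p = 0.0126 by camera). The list stayed called without any 1 array, with medians from 0.69 to 1.07. XTH19 rose 6.15-fold (log2 2.62, SE 0.29), XTH18 2.45-fold (log2 1.29, SE 0.33) and EXPA8 2.11-fold (log2 1.08, SE 0.22, adjusted p = 0.00920). WRKY53 rose 4.05-fold (log2 2.02, SE 0.30, adjusted p = 0.00120).

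MYC3 and MYC4 fell in low R/FR with JA, by 0.57 (SE 0.13, adjusted p = 0.0179) and 0.72 (SE 0.11, adjusted p = 0.00164) on the log2 scale, and both were also lower when adjusted over the list alone. Of named genes whose arrays did not overlap, the largest falls were those of AT5G62130 (-1.74), AT3G15720 (-1.72, SE 0.11, adjusted p = 1.71e-06), AT1G78020 (-1.71), AT4G19380 (-1.65), AT4G29700 (-1.57), AT5G62360 (-1.56) and AT3G19030 (-1.54). FMA fell by 0.45 (SE 0.11, adjusted p = 0.0288). The 4 anthocyanin genes missed the threshold over all probe sets and 1 was lower when adjusted over the list alone, with log2 changes from -0.60 to -0.35. In all 1399 probe sets were called, 676 higher and 723 lower, and 826 without high R/FR, JA replicate 2. HAT2 (log2 0.77, SE 0.21, adjusted p = 0.0426) lost its call without any array but high R/FR, mock replicates 1 and 3, low R/FR, mock replicate 1 and low R/FR, JA replicate 3. FMA lost it without any JA array but low R/FR replicate 1, XTH18 without JA replicate 1 or 2 of either light condition, and MYC3 without high R/FR, JA replicate 1 or low R/FR, JA replicate 1; their log2 changes ran from 0.55 to 0.92, from -0.57 to -0.38, from 0.97 to 1.67 and from -0.65 to -0.41. The low R/FR effects with mock and with JA shared 390 called rises (16.6 from independent lists) and 260 called falls (13.8), with none called in opposite directions. They correlated across probe sets at 0.73. These effects also rest on different arrays, while their tests share one estimate of the spread, so the calls are not independent.

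The interaction asked whether the JA response differed between light conditions. AT3G15720 was the 1 probe set called, with a log2 interaction of -1.40 (SE 0.15, adjusted p = 0.00897). JA raised it in high R/FR, from 3.76 ± 0.04 to 5.08 ± 0.08 (SD, n = 3), while in low R/FR it was at 3.44 ± 0.16 with mock and 3.36 ± 0.19 with JA. All these levels but that of high R/FR with JA lay in the lowest 30.2% of the probe sets of their group. At an unadjusted p under 0.05, limma gave 1287 probe sets, 5.66% of those tested. The interaction was smaller than its error for IAA29 (-0.04, SE 0.26), DFR (-0.22, SE 0.40), XTH19 (-0.38, SE 0.41) and AT5G05600 (0.27, SE 0.34). MYC4 had -0.39 (SE 0.16) and GH3.3 0.58 (SE 0.31), with adjusted p of 0.835 and 0.915. WRKY53 had 1.65 (SE 0.42) and EXPA8 0.88 (SE 0.31), with adjusted p of 0.580 and 0.753. So the calls for JA of EXPA8 in high R/FR alone, and of MYC4 and GH3.3 in low R/FR alone, were not shown to differ between light conditions, over all probe sets or adjusted over the list alone. WRKY53 missed the threshold over all probe sets, but of the 3 measured members of its list it was the 1 that passed when adjusted over the list alone (adjusted p = 0.00532), and it did so without any 1 of the 12 arrays (interaction from 1.18 to 1.91). Adjusted over the list alone, JMT of JA synthesis (-0.46, adjusted p = 0.0479, 2 measured) and JRG21 of JA breakdown (-0.57, adjusted p = 0.0334, 4 measured) also passed. JMT kept this only without high R/FR, JA replicate 2 or 3 or low R/FR, mock replicate 1 (-0.57 to -0.29 without 1 array). JRG21 lost it without high R/FR, mock replicate 1, JA replicate 1 or JA replicate 2, or low R/FR, mock replicate 1, mock replicate 2 or JA replicate 3 (-0.67 to -0.45). An adjustment over one list alone does not correct for the number of lists examined, so WRKY53, JMT and JRG21 are not established as interactions by it. Neither testable list had a called interaction (camera adjusted p = 0.666 for auxin response and 0.297 for cell wall loosening).

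Response sizes were compared over whole sets. The 1085 probe sets raised by JA on average had a median JA effect of 0.63 in high R/FR and 0.52 in low R/FR. Their median interaction was -0.11, and 68.1% responded less in low R/FR. The fry test gave p = 0.0998, which missed the threshold, while 3 of 100 draws of the permutation gave a median as far from 0. This set passed the threshold in fry with the replicate number as a block (median -0.11) and without high R/FR, JA replicate 3 (-0.16), and its median was -0.056 without low R/FR, mock replicate 1 and -0.052 without low R/FR, JA replicate 3. The 1012 lowered by JA had a median interaction of 0.039 (57.5% smaller in low R/FR, p = 0.279 by fry, 41 of 100 draws of the permutation). They passed in fry without high R/FR, mock replicate 1 (median 0.095) or JA replicate 1 (0.077), and the median was below 0 without low R/FR, mock replicate 1 (-0.039) or JA replicate 3 (-0.020). The 1188 raised by low R/FR had one of 0.016 (47.2% smaller with JA, p = 0.826 by fry, 66 of 100 draws of the permutation), and the 1255 lowered by it one of -0.078 (35.5% smaller with JA, p = 0.154, 8 of 100 draws). Single arrays moved both medians, none of them past the threshold in fry. Without low R/FR, mock replicate 1 they were -0.057 and 0.0014, with 59.4% and 50.3% smaller with JA, and without low R/FR, JA replicate 1 they were 0.078 and -0.12. The median of the raised set was also below 0 with array weights (-0.0039), and over all fits without 1 array it ran from -0.057 to 0.078.

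The average JA effect and the average low R/FR effect were then set against each other, a comparison chosen after the single contrasts had been seen. Estimates of these averages are uncorrelated by design, but their tests share one estimate of the spread per probe set. Of 678 probe sets called for both, 547 (80.7%) changed in opposite directions and 131 in the same one. JA-raised probe sets were lowered by low R/FR in 273 cases, where independent lists would share 59.9, and JA-lowered ones were raised in 274, against 52.9. The overlaps in the same direction were 62 and 69, against 56.7 and 55.8. Among named genes XTH19 (average JA effect -1.56, SE 0.21; average low R/FR effect 2.81, SE 0.21), EXPA8, XTH16, ATPMEPCRB and AT5G22460 were lowered by JA and raised by low R/FR. JAL23 (3.53, SE 0.14, and -0.76, SE 0.14), AT4G29700, UGT74B1, MYC3 and AT5G62360 went the other way. GH3.3 and MGL were raised by both, and MYC4 and BGLU47 lowered by both. In all 24 named genes were called for both, 17 of them in opposite directions. Of these, EXPA8 was called for low R/FR with JA spray alone. With mock its arrays overlapped between the light conditions, at 7.36, 8.10 and 7.86 in high R/FR and 8.04, 7.77 and 8.11 in low R/FR. XTH16 and MYC3 were not called for low R/FR with mock either. UGT74B1 was called in neither low R/FR contrast, and MYC3 in neither JA contrast.

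**Figure D2:**
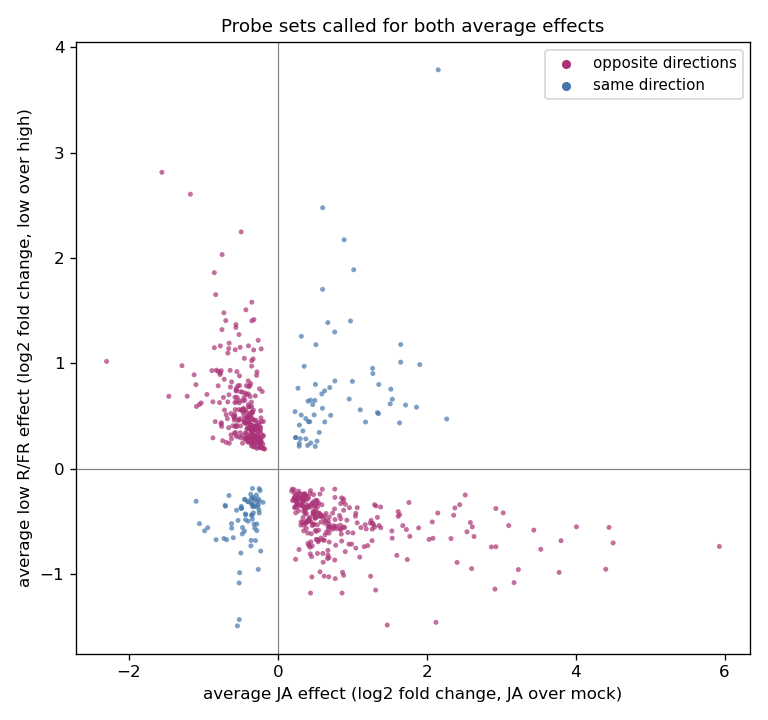
Average JA effect (horizontal axis, log2 fold change of JA over mock) against average low R/FR effect (vertical axis, log2 fold change of low over high R/FR) for the 678 probe sets called for both, 1 point each. The 547 points in the upper left and lower right parts changed in opposite directions, and 131 in the same direction.

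The fixed lists for tissue and handling had few named members. LHCB4.1, a chlorophyll-binding protein gene of mesophyll, had log2 changes between -0.05 and -0.02 in the 4 pairwise contrasts, none called by limma. It is 1 of the 19 genes of a nuclear photosynthesis list drawn up after the data had been received, and changed less in low R/FR than most of them. The median log2 change of the 19 genes was -0.12 in low R/FR with mock, where 18 lay below 0, and -0.19 with JA, where all 19 did (18 after a repeated quantile normalization). Both medians stayed below 0 when arrays were centred or normalized again. Over all probe sets 1 gene was called lower with either spray, NdhS (-0.81 and -0.92), chosen after its values were seen, and adjusted over the list alone 3 and 7 were lower. The list's camera adjusted p was 0.420 for both low R/FR effects with the estimated correlation of 0.52, and 0.000854 and 3.79e-05 with the preset one. For JA its medians were -0.025 in high R/FR and -0.064 in low R/FR, with none called by limma. The clock gene GI had changes between -0.20 and 0.06, none called. STZ (ZAT10), a gene raised by touch, had -1.26 for JA in high R/FR with an SE of 0.61, and -1.15 for low R/FR with mock. It had 0.14 for JA in low R/FR and 0.24 for low R/FR with JA. Its mean was thus highest in high R/FR with mock, but it was called in none of the 4 pairwise contrasts. SAG101, of the salicylic acid list, was called in none of them either.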

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

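The tests of the smaller JA response and of the opposite effects were chosen after these 2 patterns had been seen, as was the RNA quality covariate.

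AT3G15720 stood out because its JA effect differed between the light conditions, with a log2 interaction of -1.40. It was called without any 1 of the 12 arrays, with a value between -1.49 and -1.30. As a count of calls, 1 interaction cannot be set apart from chance: in 7 of 100 regroupings of the residuals of a model without interaction, the real one included, at least 1 probe set was called, and the highest other count was 14. Levels close to the lower end of the scale in 3 of the 4 groups limit what the fold says.

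The smaller JA response of JA-raised probe sets in low R/FR (68.1% of 1085, median interaction -0.11) missed the threshold in fry but passed it with the replicate number as a block and without high R/FR, JA replicate 3 (-0.16), while in the permutation of the residuals 3 of 100 draws gave a median as far from 0, the real one included, and the others ran from -0.13 to 0.10. With the RNA quality covariate the share was 69.4%, past the bound set beforehand for excluding poorer RNA as the whole cause. However, the control signals spread within groups mostly in low R/FR with JA (actin SD 0.64, against 0.08 to 0.23 in the other groups). The covariate thus rests largely on those arrays, and poorer RNA stays open. The lower limit of the signal is argued against by a share of 65.5% among the 772 JA-raised probe sets that were bright in both mock groups. A single array stays open: without low R/FR, JA replicate 3, the array with the largest 3' to 5' difference, the share was 59.8%, just under the bound set beforehand for excluding it, and in the JA response size by light, JA raised probe sets had a median interaction of -0.056 without low R/FR, mock replicate 1. A weaker JA response in low R/FR is the biological hypothesis, and it may be no more than a trend in these 12 arrays.

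The opposite average effects of JA and low R/FR (547 against 131 probe sets) could come from noise that single arrays bring to both averages. With both effects estimated from different arrays, the correlation across probe sets lay between -0.22 and -0.17 in 6 combinations, which argues against it. RNA quality as the whole cause is argued against by a ratio of opposite to same-direction calls of 5.35 with the covariate and 4.18 without. The covariate rests largely on the arrays of low R/FR with JA, but the ratio was also 4.11 without replicate 3 of that group. A single deviating array is argued against by a ratio of at least 3.06 without any 1 of the 12. Low R/FR moved single JA-responsive genes also without JA spray, such as XTH19 (3.00) and AT5G62360 (-1.40), while for the JA-responsive probe sets as a whole this was left undecided: in held-out mock arrays its median log2 effect on JA-raised minus that on JA-lowered probe sets was below 0 in all 3 splits (-0.11, -0.25 and -0.22), but the first of these lay between the bounds set beforehand. A different share of tissues in the petiole pieces stays open, since no vascular marker and 1 epidermis marker could be named, while the 19 nuclear photosynthesis genes had medians of -0.12 and -0.19 in low R/FR (mock and JA) and -0.025 and -0.064 for JA, so a shared set of genes driven in opposite directions by the 2 signals remains one hypothesis among others.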

How the results depend on the processing

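The RNA quality covariate and the count of opposite effects were chosen after seeing the data, and the added lists after the data had been received but before any group difference was computed. With 1 value per gene, 13356 genes were tested in place of 22746 probe sets. The counts were 516 for the JA effect in high R/FR, 321 for the JA effect in low R/FR, 473 for the low R/FR effect with mock, 680 for the low R/FR effect with JA and 254 for opposite average effects. Fewer features were tested, leaving out probe sets not paired with 1 gene. These held 54.8%, 55.4%, 50.8% and 49.2% of the main calls of the 4 pairwise contrasts. Asking for a 2-fold change gave 344, 252, 215 and 270 for the 4 pairwise contrasts, and an adjusted p under 0.01 gave 705, 438, 420 and 661. Leaving out 1 array gave 849 to 1345, 526 to 918, 517 to 1197 and 826 to 1452, with 1 to 3 for the interaction (2 without mock replicate 1 of either light condition, 3 without high R/FR, JA replicate 3) and 395 to 670 for opposite effects. eBayes with trend and robust called 3 interactions, AT3G15720 among them. The added lists had 4 calls, against 20 with camera at the preset correlation and 9 with fry, 2 tests that take less account of correlated genes or do not compare a list with other genes; the fixed lists had 6 of 10 in all 3 tests, 4 to 6 without 1 array, 4 with the covariate, and 4 without the dimmest 30% of probe sets, where the auxin list had under 5 members and was not tested. For the JA response size by light, JA raised probe sets without 1 array had median interactions of -0.16 to -0.052, past fry's threshold without high R/FR, JA replicate 3 (-0.16). In the JA response size by light, JA lowered ones had -0.039 to 0.095, past it without high R/FR, mock replicate 1 (0.095) or JA replicate 1 (0.077). Without an array the average effect and the interaction are correlated, which itself shifts these medians. The sets chosen for low R/FR missed the threshold in every fit. No called named gene or list changed sign, and of 98 calls of named genes 88 to 96 remained without 1 array. The RNA quality covariate ended 7 of the 98 (UGT74B1 for JA in high R/FR, MYC4, OPCL1, AT1G73600, AT1G23205 and EXPA15 for JA in low R/FR, HAT2 in low R/FR with JA), and array weights 4 of these (MYC4, AT1G73600, AT1G23205, EXPA15). eBayes with trend and robust ended 5 (WRKY53 for JA in high R/FR, AT1G73600 for JA in low R/FR, XTH18 in low R/FR with either spray, HAT2 with JA), and a repeated quantile normalization 1 (UGT74B1). Fitting only the groups compared ended 6 of 97 (WRKY53 for JA in high R/FR, JRG21 and AT1G73600 in low R/FR; HAT2, XTH18 and FMA in low R/FR with JA). The other settings left each count within 1.5 times its value, and recentring or renormalizing moved the share of higher calls by under 10 percentage points. Arrays give no depth; probe sets near the lower end of the scale understate changes.

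Pairing by replicate number stays open. Deviations of 18 same-number pairs correlated at a mean of 0.049 (-0.21 to 0.29, 7 above 0.1), other pairs at -0.024. Of 12 arrays 5 correlated best with their own number. With the replicate number as a block the counts were 1352, 888, 1057 and 1525 for the 4 pairwise contrasts, each higher than without it, and 1 for the interaction. The JA-raised set passed the threshold with the block (median interaction -0.11), the cause was not tested, and the cell wall list in low R/FR with mock missed it (adjusted p = 0.0665).

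Splitting the 6 arrays of a pairwise contrast otherwise makes 10 splits, too few for a share under 0.05. The real split alone (1 of 10) reached its count in each: 1240 against 0 in the others for JA in high R/FR, 801 against at most 4 for JA in low R/FR, 992 against 0 for low R/FR with mock and 1399 against 0 for low R/FR with JA. Of 100 regroupings, the real one included, 1 reached totals of 6 fixed (highest other 4) and 4 added list calls (highest other 2). Mixing all 12 arrays adds real effects to the spread, so chance is left undecided. For the 547 opposite effects (reached by 1, highest other 4) regrouping spray removes the JA calls. Same-direction calls also fell, from 131 to at most 1, so direction stays untested. Chance cannot be excluded for the medians of the JA-lowered set (41 of 100 as far from 0, real 0.039, others -0.082 to 0.14), the set raised by low R/FR (66, real 0.016, others -0.085 to 0.10) or the set lowered by it (8, real -0.078, others -0.12 to 0.089).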

Other observations

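The tests of the 16 lists reported here were chosen after the data had been received, before any group difference was computed, and 1 of the lists was called for JA. Its flavonoid and anthocyanin genes rose in both light conditions, 7 of 9 each (and 7 each when adjusted over the list alone), with median log2 changes of 2.49 in high R/FR and 2.39 in low R/FR and camera adjusted p of 0.0135 and 0.0131. Beyond the fixed list, UGT78D2, a flavonoid glycosyltransferase gene, rose by 2.49 (SE 0.12) and 2.39 (SE 0.12), and UGT78D1 by 1.35 (SE 0.12) and 0.97 (SE 0.12). UGT78D1 also fell in low R/FR, by 0.55 with mock and by 0.93 with JA. BAN had log2 changes of -0.03 and 0.09 for JA, not called. Glucosinolate genes had 5 of 7 and 4 of 7 called higher with JA, and the list missed the threshold (adjusted p = 0.109 and 0.0810 with an estimated correlation). The glucosinolate transporter gene GTR2 rose by 0.73 (SE 0.11) and 0.65 (SE 0.11), and fell by 0.49 in low R/FR with JA. Genes named here outside the fixed lists were chosen after their values were seen.

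The merged shade and auxin list rose in low R/FR, 5 of 8 with either spray (camera adjusted p = 0.00837 with mock and 0.0131 with JA). The other 13 added lists had no called contrast. The lowest adjusted p was 0.164 for the merged JA lists, 0.296 for the XTH and expansin families (median log2 changes of -0.16 and -0.089 for JA in high and low R/FR, and of 0.019 and 0.12 in low R/FR with mock and JA), 0.416 for defence signalling, 0.912 for calmodulin-like calcium sensors, 0.303 for gibberellin perception, 0.416 for UDP-glycosyltransferases, 0.366 for tau glutathione transferases, 0.420 for beta-glucosidases, 0.420 for SWEET transporters, 0.357 for the CYP71B family, 0.420 for autophagy genes, 0.420 for nuclear photosynthesis genes and 0.871 for plastid-encoded genes. With the preset correlation the nuclear photosynthesis genes were called in both low R/FR contrasts (0.000854 with mock and 3.79e-05 with JA), and fry gave 0.175 and 0.101. Other lists were called with it too. For JA in high R/FR the merged JA lists had 4.46e-06 (0.00797 by fry), and the XTH and expansin families 0.00314 (0.0132 by fry). All 15 defence signalling genes had an interaction above 0 (median 0.23). For this list camera gave 0.00314 with the preset correlation and 0.416 with the estimated one of 0.23, and fry 0.305. The 69 plastid-encoded genes had median log2 changes of -0.046 in low R/FR with mock and -0.048 with JA, and of 0.0035 and 0.0048 for JA in high and low R/FR. The median for JA in high R/FR was below 0 after a repeated quantile normalization (-0.012). Within families, single members moved apart: the vacuolar sugar transporter gene SWEET16 rose with JA by 1.31 (SE 0.13) in high R/FR and 1.08 (SE 0.13) in low R/FR, while SWEET2 fell by 0.71 (SE 0.14) with JA in low R/FR. EXLA2, an expansin-like gene, rose in low R/FR by 1.16 (SE 0.15) with mock and 1.35 (SE 0.15) with JA, with JA effects of -0.13 and 0.06 that were not called.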
